A study of Homo sapiens with 8 samples.

How the data were processed

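MicroRNAs (miRNAs) were measured in total RNA from Huh7 cells, an established human hepatocellular carcinoma line, on 1-colour Agilent human miRNA arrays. There were 8 arrays, 4 from cells named WT and 4 from stable transfectants of Gα12QL, an activated mutant of the G protein subunit Gα12. Per the labels' protocols, transfectants were selected with Geneticin for 3 weeks, all cells were deprived of serum for 24 h before harvest, and 100 ng of RNA per sample was labelled with Cy3. The titles call the control cells wild-type while the protocol text also mentions transfection with an empty vector, so it stays unclear whether the control cells went through selection. The 4 samples of a group came from separate plates. Nothing in the labels says that they came from separate transfections, so the p-values measure only the spread between plates and arrays.

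Each scanner file held 14907 spots, of which 14192 belonged to human miRNAs, with 2446 probes for 887 miRNAs. The deposited values were spot intensities on a linear scale, extracted with Feature Extraction version 10.7.3.1 per the file headers and with Agilent Feature Extraction 10.7.5.1 per the submitters' processing notes. The processed intensity was background-subtracted by that software per the file headers and was not normalized between arrays. A value table of 886 miRNAs was also deposited by the authors. Set against the scanner's summed miRNA signal, 236 of its miRNAs were bright enough (signal over 20 on all arrays of a group) to be classified. Of these, 90 lay on the linear scale within 1.5 log2 units, 144 matched log2 differences from WT, and 2 stayed undecided. The table held 9 missing values. Its column medians were 0.0438, 0.131, 0.110 and 0.0904 for WT replicates 1 to 4 and 0.0472, 0.174, 0.282 and 0.312 for Gα12QL replicates 1 to 4. Its normalization, and the scale of dim miRNAs, are not given in the sources used here, and it was used only as an alternative.

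For the main values, control spots and spots marked as population or non-uniformity outliers (6.83% to 9.99% of the human miRNA spots per array) were left out, and the processed signals of a probe's spots were averaged. A probe was called well above background on an array where over 50% of its spots carried that flag. Each array was divided by its 75th percentile over the 391 probes well above background on all 8 arrays. Signals were then raised to a common floor of 0.0224 (the median over arrays of the 5th percentile of probes well above background), which is -5.48 in log2, and log2-transformed. A miRNA with several probes took its brightest probe. No tested miRNA had detected probes that moved in opposite directions by over 0.2 log2 units, among the 257 with more than 1 detected probe. In size, detected probes of a miRNA could still disagree. Their log2 fold changes spanned 2.64 for miR-10b, 2.59 for miR-145, 2.42 for miR-100 and 2.29 for miR-222. The errors given below do not include this spread. All levels below are log2 signals relative to the array's 75th percentile, and they compare the same miRNA between groups, not different miRNAs.

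A miRNA was tested where its probe was well above background on at least 3 of the 4 arrays of a group, which held for 330 of 887. The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Changed", "rose" and "fell" refer to that threshold, and errors of log2 fold changes are limma's moderated standard errors (SE). Where a miRNA was below background on all arrays of a group, the fold is given as a lower bound. The bound sets the bright group's mean log2 signal against, per array, the higher of the lowest signal well above background and the miRNA's own signal. That lowest signal (mean log2 -6.05 over WT and -5.60 over Gα12QL arrays) lies below the common floor, so a bound can exceed the fold between group means at the floor (459-fold for let-7i). Bounds hold for the processed signals only. For such miRNAs the floor removes the spread within the dim group, so their limma errors are too small. The floor likewise sets the size and error of change of miR-200c, miR-487b and miR-24-1*, which were above background on some or all arrays of a group but at the floor on all 4, and in part those of let-7d, miR-145, miR-148a, miR-196b and miR-654-5p, which were at the floor on some arrays.

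From textbook knowledge, 19 lists of miRNAs were fixed before the data were examined, and 17 with at least 2 tested members were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Array-level values were compared by exact two-sided permutation tests over 70 assignments, whose smallest p is 0.0286. The miRNAs to name were also fixed beforehand by rule. The rule took the 12 largest increases and the 12 largest decreases among changed miRNAs whose arrays did not overlap between groups, 14 miRNAs named in advance (miR-34a, miR-192, miR-194, miR-215, miR-200a, miR-200b, miR-200c, miR-141, miR-429, miR-122, miR-21, miR-16, let-7a and let-7i), and the 5 brightest. It added at most 4 examples per list, those with the smallest p. miRNAs named outside it are marked as chosen after their values were seen.

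The replicate numbers were checked for pairing. Deviations from the group means correlated between same-numbered WT and Gα12QL arrays at 0.649, 0.262, 0.503 and 0.489 across miRNAs, so by the rule set beforehand (all above 0.1) the numbers pair the arrays. For replicate 4, though, the best match in the other group was replicate 3. The replicate number coincides with the column of the array on the slide, so pairs and columns cannot be told apart. All 8 arrays sat on 1 slide scanned on 1 day, with WT in the first row and Gα12QL in the second, so slide row and group cannot be told apart, and no slide or scan block could be fitted. Alternatives covered other normalizations, background corrections, probe summaries, detection filters, floors and variance models, the deposited value table, the replicate number as a block, and each array left out in turn. The files held raw medians but no mean signals, so the normexp background correction (offset 50) used the median signals. The array's miRNA names follow an old miRBase release and were kept. The header's genome build differs from the gene table at hand (GRCh38.p14), so no coordinates are given, and that table served only to find neighbouring miRNA genes.

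The limma step was tested on simulated arrays for the Gα12QL against WT comparison, with 330 miRNAs and 20 runs. It called 27.2% of miRNAs changed 1.1-fold, 78.2% of those changed 1.25-fold, 91.8% at 1.5-fold and 97.8% at 2-fold, and 1.26% of unchanged ones. Most simulated values were unchanged (5000, against 400 at each fold). In the data 83.6% of tested miRNAs changed, so these rates need not carry over. A list raised 2-fold was recovered by camera with 0 of 16 other lists called. Tests of the closing section and figures were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.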

Results

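The series compared miRNA levels in Huh7 cells that stably carry activated Gα12 (Gα12QL) with those in WT Huh7 cells, with 4 plates and 4 arrays in each group. Gα12 is the α subunit of a heterotrimeric G protein. The question was which miRNAs differ when Gα12 is constitutively active in a liver cancer line. Arrays of one group were close to each other. Pearson's r across the 330 tested miRNAs was 0.990 to 0.999 among WT arrays and 0.989 to 0.999 among Gα12QL arrays, but 0.687 to 0.705 between groups. The median absolute difference between arrays was 0.0392 to 0.141 log2 units among WT arrays, 0.0568 to 0.136 among Gα12QL arrays and 0.944 to 1.11 between groups. miRNAs are not independent replicates, so these values describe the arrays only.

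miR-122 and miR-148a, miRNAs typical of liver cells, were far lower in Gα12QL cells, and let-7i, miR-10a and miR-100 were far higher. miR-122, the most abundant miRNA of adult hepatocytes, was at 2.13 ± 0.05 (SD, n = 4) in WT and below background on all 4 Gα12QL arrays, at least 212-fold lower (limma adjusted p = 1.38e-13). miR-148a was at 2.44 ± 0.05 in WT, was above background on 2 of 4 Gα12QL arrays and at the floor on 3, and had a log2 fold change of -7.90 (SE 0.03), whose size depends on the floor. In the other direction, let-7i was below background on all WT arrays and at 3.36 ± 0.14 in Gα12QL, at least 680-fold higher (limma adjusted p = 3.92e-12). miR-10a, encoded in a HOX cluster, was at least 223-fold higher and also below background on all WT arrays.

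Across all miRNAs, 276 of 330 tested changed (83.6%), with 146 higher and 130 lower in Gα12QL and 54 not past the threshold. The balance turned under other scalings, with 145 of 270 changed miRNAs lower under quantile normalization, 142 of 263 without scaling and 147 of 265 with the percentile over all probes. Changes of at least 2-fold numbered 90 higher and 75 lower, and changes of at least 8-fold 29 higher and 18 lower. The 4 arrays of one group lay wholly above the 4 of the other for 268 of the 330, where chance gives 2.86%. Of the tested miRNAs, 35 were below background on all WT arrays and 47 on all Gα12QL arrays. These were tested only through the other group, so where their arrays part, the filter and the floor largely account for it.

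Large increases, next to let-7i and miR-10a, were also those of miR-886-3p, a fragment of the vault RNA gene VTRNA2-1 rather than a canonical miRNA (at least 206-fold), let-7d (log2 fold change 6.53, SE 0.06, above background on 3 of 4 WT arrays), let-7g (6.35, SE 0.06), let-7b (5.64, SE 0.27), miR-135b (at least 62.3-fold), miR-98 of the let-7 family (at least 57.9-fold) and miR-100 (5.30, SE 0.05). Both strands of the miR-30a hairpin rose, miR-30a by 4.81 (SE 0.04) and miR-30a* by 5.33 (SE 0.06), and miR-29b-1* rose by 4.53 (SE 0.06). Large decreases, next to miR-122 and miR-148a, included miR-122* (at least 51.8-fold), miR-483-3p, which lies in the IGF2 gene (at least 45.2-fold), miR-200b (at least 43.7-fold), miR-224 (at least 37.5-fold) and miR-885-5p (at least 26.2-fold). miR-103 and miR-107, a closely related pair tied to insulin sensitivity, each had a log2 fold change of -5.10 (SE 0.05). The log2 fold change was -4.69 (SE 0.03) for miR-215, -4.47 (SE 0.03) for miR-194 and -4.37 (SE 0.06) for miR-192, 3 miRNAs enriched in liver and gut.

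The 5 miRNAs with the highest mean signal over all 8 arrays differed by at most about 2-fold. miR-21, a miRNA raised in many tumours, was the brightest on all arrays, at 7.61 ± 0.19 in WT and 8.64 ± 0.07 in Gα12QL. It rose by 1.04 (SE 0.10, limma adjusted p = 1.87e-05), but by 0 under quantile normalization, which gives the brightest probe of each array an equal value. It made up 30.0% to 35.1% of the summed miRNA signal on WT arrays and 42.4% to 43.7% on Gα12QL arrays. miR-720, a tRNA fragment, did not pass the threshold (log2 fold change -0.15, SE 0.07, limma adjusted p = 0.0882), but passed it without WT replicate 1 (-0.24, adjusted p = 0.0252), under quantile normalization (-0.47, adjusted p = 2.10e-08), with the percentile over all probes (-0.45, adjusted p = 0.0211) and with the mean over probes (-0.21, adjusted p = 0.0217). miR-1974_v14.0, which matches a mitochondrial tRNA, rose by 0.78 (SE 0.08), while miR-22 fell by 0.25 (SE 0.08) and miR-19b by 0.23 (SE 0.06). With the deposited value table, miR-1974_v14.0 (0.42, adjusted p = 0.140) and miR-22 (-0.54, adjusted p = 0.0517) did not pass the threshold, nor did miR-22 without a detection filter (adjusted p = 0.0705).

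**Figure D1:**
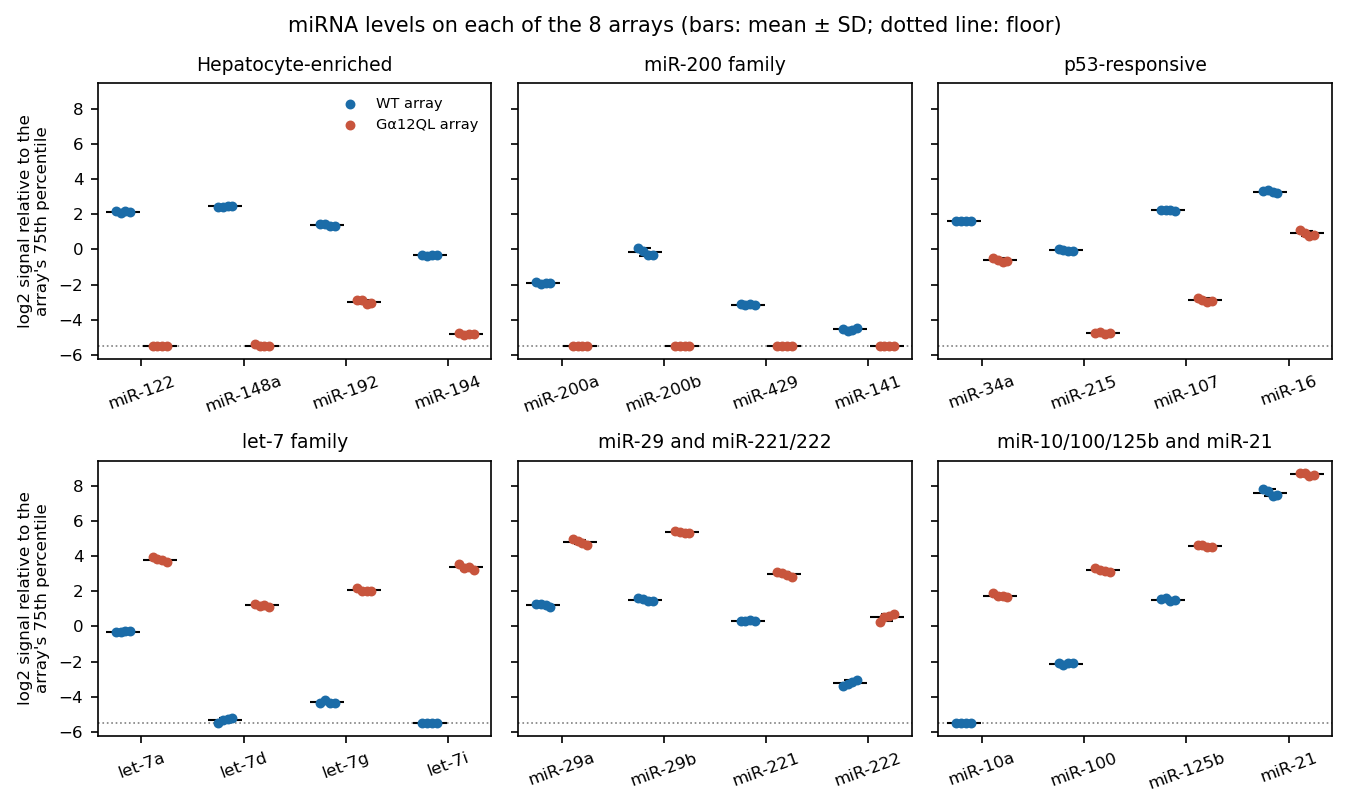
Log2 signal relative to the array's 75th percentile for 24 named miRNAs, with 1 point per array (blue WT, red Gα12QL), bars for the mean ± SD of 4 arrays and a dotted line at the floor of -5.48. The WT and Gα12QL arrays are separate for each miRNA shown, with miR-122 at the floor on all 4 Gα12QL arrays and let-7i at the floor on all 4 WT arrays.

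The limits of this comparison are the plates, which may stem from 1 transfected pool, and the slide row, which holds 1 group each. Probes of closely similar miRNAs can read each other's signal, so single members are less certain than their group. Examples are let-7 members, miR-103 and miR-107, miR-23a and miR-23b, and miR-27a and miR-27b. Others are miR-10a and miR-10b, miR-192 and miR-215, miR-18a and miR-18b, and miR-29a and miR-29c. The normexp background shrank large changes, to a log2 fold change of 6.26 for let-7i, 4.81 for miR-10a, 3.18 for miR-135b, -5.11 for miR-122, -2.98 for miR-200b and -2.81 for miR-224.

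Grouped by the lists fixed beforehand, the let-7 family was called higher, and the hepatocyte-enriched, miR-200, miR-17-92 and p53-responsive lists lower. All 5 calls were lost with an estimated correlation (adjusted p = 0.384 to 0.459), and those of the p53-responsive and miR-17-92 lists also under other scalings, as given below. All 9 members of the let-7 family, which restrains RAS and MYC and marks differentiated cells, rose, and 9 did so adjusted over the list alone. The median log2 fold change was 5.29, or 5.64 with miRNAs below background at their bound (camera adjusted p = 0.00115, and adjusted p = 0.384 with an estimated correlation). let-7a rose by 4.08 (SE 0.06), from -0.29 ± 0.03 to 3.79 ± 0.12.

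In the hepatocyte-enriched list 9 of 10 tested members fell and 1 rose, and 10 changed adjusted over the list alone. The median was -4.42 (camera adjusted p = 0.00168, and adjusted p = 0.384 with an estimated correlation). Both strands of the miR-122, miR-192, miR-885 and miR-148a hairpins count as members, so the members are not independent. The preset correlation takes little account of this. The p53-responsive and neural lists also hold both strands of some hairpins. The member that rose, miR-101, which targets the histone methyltransferase EZH2, had a log2 fold change of 0.35 (SE 0.05) and did not pass the threshold without scaling or with the percentile taken over all probes. The list is not called among miRNAs detected on all 8 arrays (adjusted p = 0.267), where miR-122 and the other members lost in Gα12QL cannot enter. Of its members 10 were detected in WT and 3 in Gα12QL, while neural miRNAs went from 1 to 8, blood cell miRNAs from 2 to 1 and stromal miRNAs from 2 to 3.

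All 5 tested members of the miR-200 family, which holds epithelial cells together by repressing ZEB1 and ZEB2, fell, and 5 did so adjusted over the list alone. The median was -2.34, or -2.46 with bounds (camera adjusted p = 0.0128, and adjusted p = 0.384 with an estimated correlation). miR-200b, miR-200a, miR-429 and miR-141 were below background on all Gα12QL arrays, at least 43.7-fold, 12.9-fold, 5.49-fold and 2.07-fold lower. miR-200c was above background on 1 of 4 Gα12QL arrays but at the floor on all 4, so it was called lower (log2 fold change -1.15) with a size set by the floor. With the normexp background, miR-141 (log2 fold change -0.11) and miR-200c (-0.19) did not pass the threshold.

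In the p53-responsive list, miRNAs induced by the tumour suppressor p53 or processed with its help, 9 of 13 tested members fell, 3 rose and 1 was not past the threshold, and 12 changed adjusted over the list alone. The median was -2.21 (camera adjusted p = 0.0355, and adjusted p = 0.435 with an estimated correlation). The study has itself pursued p53-responsive miRNAs in these cells, so this list is not independent evidence of its direction. Nor is it separate from other lists. Its members miR-192, miR-192* and miR-194, which fell, also belong to the hepatocyte-enriched list. miR-15a and miR-16, which also fell, belong to the miR-15/16 family. miR-34a, the best known p53 target among miRNAs, went from 1.61 ± 0.02 to -0.60 ± 0.10, a log2 fold change of -2.21 (SE 0.05, limma adjusted p = 2.52e-09). miR-192, miR-194, miR-215 and miR-107, given above, fell by more, and miR-16, a brake on the cell cycle, fell by 2.37 (SE 0.07). The 3 that rose were miR-145 (3.02, SE 0.11), a smooth muscle miRNA, and miR-34b and miR-34c-3p, which were below background on all WT arrays (at least 3.84-fold and 4.31-fold higher). The other strands of these hairpins, named after their values were seen, did not rise. miR-34b* fell (-0.85, SE 0.05) and miR-34c-5p was not past the threshold (-0.12, SE 0.10). The list's call was lost under quantile normalization, without scaling, with the percentile over all probes and with Agilent's gene signal, at adjusted p between 0.0518 and 0.0624.

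Of the miR-17-92 cluster and its paralogues, miRNAs driven by MYC that promote proliferation, 11 of 12 tested members fell, 1 rose, and 12 changed adjusted over the list alone. The median was -0.59 (camera adjusted p = 0.0211, and adjusted p = 0.459 with an estimated correlation). miR-18a fell by 1.82 (SE 0.04), miR-18b by 1.80 (SE 0.02) and miR-93 by 1.13 (SE 0.04), while miR-363 was below background on all WT arrays and at least 3.42-fold higher in Gα12QL. The call was lost without scaling, with the percentile over all probes and with Agilent's gene signal (adjusted p = 0.0518 to 0.0629), and with the deposited value table (adjusted p = 0.418).

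The miR-29 family and the neural list were called higher. All 3 members of the miR-29 family, repressors of collagen and DNA methyltransferase genes, rose, and 3 did so adjusted over the list alone, by 3.83 for miR-29b (SE 0.05), 3.58 for miR-29a (SE 0.07) and 2.36 for miR-29c (SE 0.02). The camera adjusted p was 0.0468, against an adjusted p = 0.384 with an estimated correlation and 0.0526 with the replicate number as a block. The miR-29 call was lost in 12 of 22 alternatives. Among them were no scaling (adjusted p = 0.0570), the percentile over all probes (0.0529), Agilent's gene signal (0.0518) and a lower floor (0.0547). Others were miRNAs detected on all arrays (0.0711) and the deposited value table (0.117). It was also lost without WT replicate 1 (0.0578), WT replicate 2 (0.0504), WT replicate 3 (0.0501) or Gα12QL replicate 3 (0.05001). Quantile normalization kept it (0.0270). Among neural miRNAs, 7 of 8 tested members rose and 1 fell, and 8 changed adjusted over the list alone. The median was 1.54, or 2.11 with bounds (camera adjusted p = 0.0355, adjusted p = 0.384 with an estimated correlation, and 0.0526 with the replicate block). The neural call was also lost with the normexp background (adjusted p = 0.182) and the deposited value table (0.115). Only miR-128, the member that fell (-1.15, SE 0.08), was detected on at least 3 WT arrays, against 8 of the 9 listed on Gα12QL arrays. miR-129-3p, miR-138, miR-9 and miR-9* were below background on all WT arrays and at least 22.9-fold, 11.4-fold, 8.27-fold and 4.32-fold higher.

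The other lists were not called. In the miR-15/16 family 5 of 7 fell, 1 rose and 1 was not past the threshold, with 6 changed adjusted over the list alone (median -2.25, camera adjusted p = 0.0635). miR-15a fell by 2.54 (SE 0.08) and miR-15b by 2.25 (SE 0.06), and miR-424, which rose by 0.65 (SE 0.10), was not past the threshold under quantile normalization. The list was called without Gα12QL replicate 1 (adjusted p = 0.0495). The clusters of miR-23, miR-27 and miR-24 parted, with miR-23a up by 1.99 (SE 0.04) and miR-27a by 1.90 (SE 0.07), and miR-23b down by 2.39 (SE 0.06) and miR-27b by 2.12 (SE 0.05). All 5 tested members of these clusters changed over all miRNAs and 5 adjusted over the list alone (camera adjusted p = 0.771). miR-221 and miR-222, which repress the cell cycle inhibitor p27, both rose, by 2.65 (SE 0.06) and 3.73 (SE 0.11), and 2 changed adjusted over the list alone (camera adjusted p = 0.165).

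In the family of miR-10, miR-99, miR-100 and miR-125b 4 rose and 3 fell, and 7 changed adjusted over the list alone (camera adjusted p = 0.414). miR-10b was at least 25.9-fold higher and miR-125b rose by 3.04 (SE 0.05). In the miR-30 family 3 rose and 2 fell, and 5 changed adjusted over the list alone (camera adjusted p = 0.710), with miR-30e up by 0.25 (SE 0.04), miR-30b down by 0.88 (SE 0.04) and miR-30d down by 0.75 (SE 0.07). The rise of miR-30e was not past the threshold without scaling or with the percentile over all probes. In the miR-181 family miR-181c fell by 0.60 (SE 0.10) and miR-181d by 0.68 (SE 0.13), miR-181b was not past the threshold (0.04, SE 0.04), and 3 of 4 changed adjusted over the list alone (camera adjusted p = 0.710). miR-181a passed it barely (0.10, SE 0.04, limma adjusted p = 0.0354) and did not pass it without any 1 array except WT replicate 2 (adjusted p = 0.0532 to 0.446). Its sign turned under quantile normalization, without scaling and with the percentile over all probes. With the normexp background, miR-181c (-0.13, adjusted p = 0.104) and miR-181d (-0.22, adjusted p = 0.0593) did not pass the threshold. Among miRNAs often raised in hepatocellular carcinoma 7 of 16 were higher, 7 lower and 2 not past the threshold, with 14 changed adjusted over the list alone (camera adjusted p = 0.458). Without scaling these were 5 higher and 8 lower, and under both quantile normalization and the percentile over all probes 3 higher and 9 lower. miR-452, which shares a host gene with miR-224, was at least 8.77-fold lower.

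Lists of other cell types were mostly below background. Of 9 stromal, endothelial and stellate miRNAs 3 were tested, miR-10b and miR-145 rose, and 2 changed adjusted over the list alone (camera adjusted p = 0.1995). miR-126, the endothelial marker among them, had a log2 fold change of 0.03 (SE 0.08), and fell with the percentile over all probes (-0.26, adjusted p = 0.0190). Of 10 blood cell miRNAs 2 were tested and 2 changed adjusted over the list alone (camera adjusted p = 0.851). miR-146a, a brake on NF-κB signalling, rose by 1.12 (SE 0.04), and miR-451, an erythroid miRNA, was at least 3.76-fold lower. None of the 7 muscle miRNAs was tested, since 0 were detected on 3 arrays of a group. Of 44 miRNAs of the C19MC cluster, active in placenta, 1 was tested, miR-498, which was at least 5.94-fold higher and changed adjusted over the list alone. Of 65 miRNAs of the imprinted DLK1-DIO3 cluster 5 were tested, 2 rose, and 2 changed adjusted over the list alone (camera adjusted p = 0.414). miR-134 was at least 6.71-fold higher, miR-487b was called higher (log2 fold change 0.83) from the floor on all 4 WT arrays, which sets that size, and miR-494 (0.58, SE 0.34) and miR-654-5p (0.69, SE 0.45) were not past the threshold. With the replicate block, miR-654-5p passed the threshold (adjusted p = 0.0469) and miR-181a did not (0.0785). miR-654-5p also passed it with a lower floor (1.99, adjusted p = 0.0230) and with Agilent's gene signal (1.62, adjusted p = 0.0333). Without WT replicate 1, miR-494 passed it, with a log2 fold change of 0.89 (adjusted p = 6.41e-05).

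**Figure D2:**
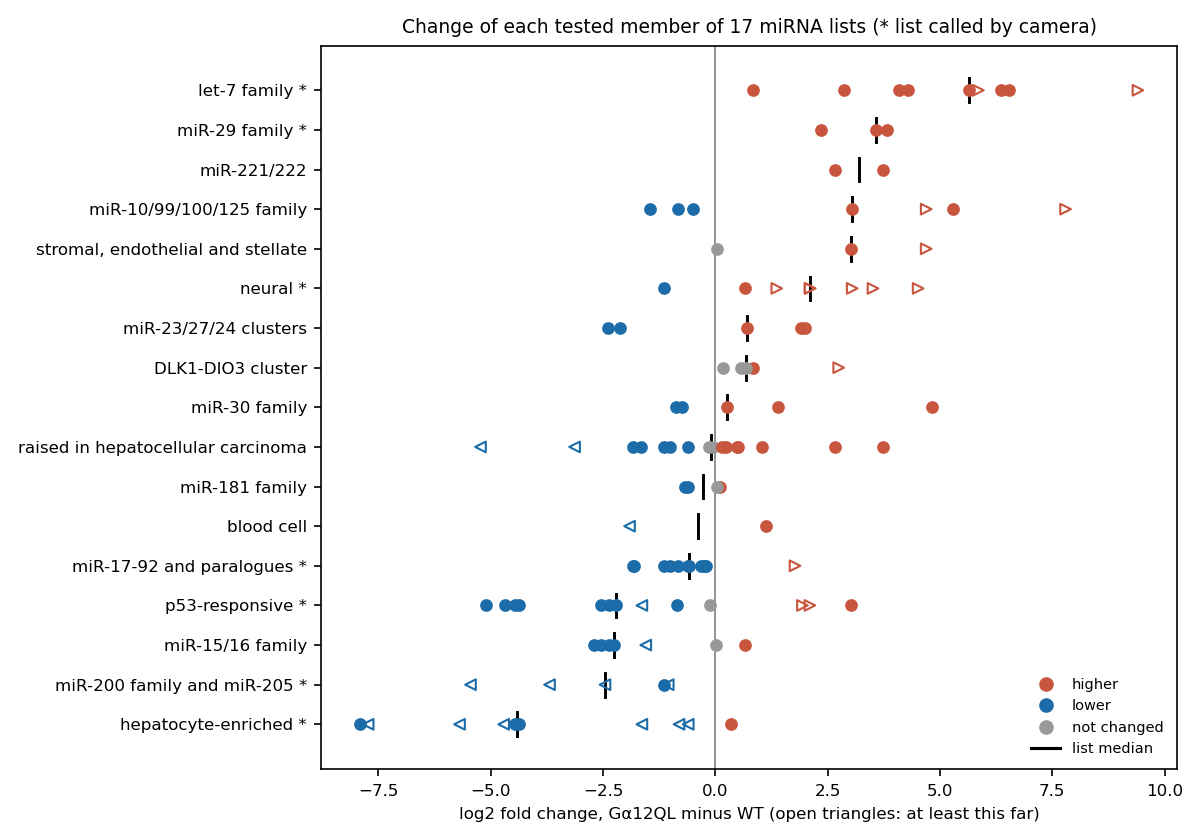
Log2 fold change (Gα12QL minus WT) of each tested member of 17 miRNA lists, coloured by call, with open triangles where 1 group was below background and the value is a bound, and a bar at each list's median. The 9 let-7 members lie right of 0 and the 5 miR-200 members left of 0, and asterisks mark the 7 lists called by camera.

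In all, 7 of 17 lists were called by camera with the preset correlation, 0 by camera with an estimated correlation (1 at an unadjusted p under 0.05) and 17 by fry, which asks only whether a list's members move on balance one way. In the main setting, no list's median, mean and test differed in sign. For the clusters of miR-23, miR-27 and miR-24 the mean turned negative under quantile normalization (-0.44), without scaling (-0.21) and with the percentile over all probes (-0.28), while median and test stayed positive, and for the miR-30 family the median turned negative with the percentile over all probes (-0.04). Over all alternatives, some with fewer members tested, 3 other medians also changed sign. They ran from -0.49 to 3.07 for the family of miR-10, miR-99, miR-100 and miR-125b, and from -1.42 to 0.23 for blood cell miRNAs. For miRNAs often raised in hepatocellular carcinoma the range was -0.66 to 0.05.

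The number of miRNAs detected was 293.5 ± 7.85 in WT (SD, n = 4) and 275.75 ± 14.03 in Gα12QL (SD, n = 4), a difference of -17.75 (exact permutation test, two-sided p = 0.0857). It was lower in Gα12QL in all 4 same-numbered pairs, with differences of -10, -14, -11 and -36 (exact sign-flip permutation, two-sided p = 0.125, the smallest 4 pairs can give). Without Gα12QL replicate 3, on which 293 were detected, the difference was -23.5 (exact permutation p = 0.0286). The 75th percentile used for scaling was 9.07 ± 0.26 in WT and 8.84 ± 0.08 in Gα12QL on the log2 scale, a difference of -0.23 (exact permutation test, two-sided p = 0.171). Without WT replicate 1, the dimmest WT array at 8.72, it was -0.35 (exact permutation p = 0.0286).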

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

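All tests of explanations in this part were chosen after the results were seen. Of 123 sets of 4 arrays examined (named miRNAs above the floor in a group, and the array-level values), 9 had 1 array far from the other 3, measured as its gap to the nearest array over the range of all 4. Chance gives about 1 in 20. On Gα12QL replicate 1, let-7g stood at 2.16 against at most 2.01 (gap over range 0.961), let-7b at 1.24 against 1.03 to 1.07 (0.837), miR-103 at -2.73 against -2.87 to -2.85 (0.861), miR-15b at 1.13 against 0.89 to 0.92 (0.857), miR-9* at -3.86 against -3.97 to -3.95 (0.849) and miR-181c at -4.82 against -4.53 to -4.48 (0.845). These gaps are small beside the differences between groups, except for miR-181c, whose log2 fold change was only -0.60. miR-27a on Gα12QL replicate 3 stood at 4.46 against 4.55 to 4.56 (0.880), and miR-29c on WT replicate 4 at -1.10 against -1.05 (0.9). The widest gap was that of miR-494 on WT replicate 1, at 0.51 against -1.05 to -0.84 (0.863), and without that array miR-494 was called higher (log2 fold change 0.89, adjusted p = 6.41e-05, in a range of 6.41e-05 to 0.361 over its alternatives).

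Among control features, which no comparison used, mr_1 was 1.97-fold brighter on Gα12QL arrays, at 4139 ± 362 against 2098 ± 95.6 (median spot signal, SD, n = 4, exact permutation p = 0.0286, the smallest this design can give). hur_6 was 2.99-fold dimmer (exact permutation p = 0.0286), hur_2 was 1.13-fold dimmer (exact permutation p = 0.0286), hur_5 was 1.38-fold dimmer (exact permutation p = 0.0857), and hur_1 and hur_4 differed by 1.02-fold and 1.04-fold (exact permutation p = 0.857 and 0.457). What these features bind is not given in the sources used here.

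Of 10 hepatocyte-enriched miRNAs tested 9 were lower in Gα12QL, miR-122 to below background, and technical explanations were tested. A single array under the wrong label is argued against by the correlations, since the lowest r within a group was 0.989 and the highest between groups 0.705. A mixture of other cells with a sizeable share of WT cells is argued against by the little left of WT levels in Gα12QL. This holds if the WT cells in such a mixture kept their levels. For miR-122, 0.472% was left by its bound on the processed signals, which is no strict upper limit. Between group means at the floor it was 196-fold lower. With the normexp background its log2 fold change was -5.11, which leaves more. RNA of another cell line or culture on all 4 Gα12QL arrays cannot be told apart from an effect of Gα12QL, because both would separate the groups as seen (highest r between groups 0.705) and no genotype or transgene was measured here. Slide row is confounded with group in the same way, and an effect of activated Gα12 or of selecting a subclone stays open as untested biology.

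The rise of the let-7 family could reflect probes that read 1 common signal, but the 7 members measured in both groups differed in log2 fold change by 5.70, more than such a signal allows. Partial cross-reading between members stays open. A candidate explanation is a rise in let-7 maturation without transcription of the host clusters. let-7c and let-7e rose by 2.87 and 0.83 log2 units. miR-99a, miR-99b and miR-125a-5p, which are encoded beside them, fell (log2 fold changes -0.83, -1.45 and -0.49). The smallest of the 3 differences between a let-7 member and a neighbour was 1.32 log2 units, for let-7e against miR-125a-5p. Only 3 neighbours in 2 host clusters were compared. miR-100 and miR-125b, of the same family as these neighbours, also have genes beside let-7 genes but were not compared. They rose by 5.30 and 3.04 log2 units, and miR-125b-2*, from the cluster of let-7c, by 0.60 (SE 0.11). Not all neighbours of let-7 genes thus fell, so a rise in transcription stays open. Probes of let-7c and let-7e can read let-7a, and 0 of 9 let-7 star strands on the array could be tested. Maturation, transcription and cross-reading thus cannot be told apart. For let-7 members outside these clusters, transcription of the host genes stays open as well.

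Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave changed miRNAs by limma (276, against 0). At an unadjusted p under 0.05 the others gave 0 to 19, against 277. Every other split mixes arrays of both groups, which widens the spread within each side. A count of 0 was therefore likely in advance, and chance is not excluded by it. For the lists, 1 of the 35 splits called as many as 7, and the highest other called 6. At least 1 list was called by 24 of the 34 other splits, with 0 changed miRNAs. Splits with 3 or 1 WT arrays in the first group keep part of the real difference, and they called 3 to 6 lists. Those with 2 called at most 1. The list counts thus do not show how often chance alone calls a list, and are not read as excluding chance. By the rule set beforehand the replicate numbers pair the arrays. Among the 8 splits that part all 4 same-numbered pairs, as the real split does, the other 7 gave 0 changed miRNAs and at most 4 lists. For both counts, 8 splits are too few for a share under 0.05.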

How the results depend on the processing

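Only the sign flips within same-numbered pairs for the number of detected miRNAs (exact permutation p = 0.125) were chosen after the results were seen. Of 1460 comparisons of a named miRNA with its value under an alternative, 1425 kept direction and side of the threshold, 22 lost and 8 gained the call, and 5 turned. miR-181a turned under quantile normalization (-0.0048), without scaling (-0.13), with the percentile over all probes (-0.19) and with the deposited value table (-0.23), and miR-126 with the percentile over all probes (-0.26). The cause was not tested. These scalings moved the median of all miRNAs down, from 0.09 in the main setting, by 0.101 (quantile), 0.161 (no scaling) and 0.183 (all probes) log2 units. miR-21 came to 0 under quantile normalization by construction.

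The number of changed miRNAs was 181, with 81 lower, among the 207 detected on all 8 arrays, since fewer miRNAs were tested. It was 171, with 79 higher, among the 234 usable in the deposited value table, where fewer miRNAs were tested and 41 calls were lost. Under the other alternatives it lay between 235 and 292, and between 269 and 282 with 1 array left out. The deposited table gave the same sign as the scanner values for 214 of 234 miRNAs. These 234 had been kept, and given a scale, by their match to the scanner signal. Equal signs were therefore likely in advance, and the share is no independent check. Called lists numbered 4 without scaling, with the percentile over all probes and with Agilent's gene signal, 3 among miRNAs detected on all arrays, 3 with the value table, 0 with an estimated correlation and 17 with fry. The cause was not tested. With 1 array left out they numbered 6 to 8. Over all alternatives, fry included, the highest adjusted p was 0.384 for the let-7, hepatocyte-enriched, miR-200, miR-29 and neural lists, 0.435 for the p53-responsive and 0.459 for the miR-17-92 list, and the lowest was at most 3.93e-07 for each. Gained list calls were 10 under fry, and those of miR-15/16 with the normexp background (adjusted p = 0.0489), without a detection filter (0.00888) and without Gα12QL replicate 1. Without a detection filter 2 further lists were called, miR-221 and miR-222 (adjusted p = 0.00643) and the family of miR-10, miR-99, miR-100 and miR-125b (0.0329).

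With the replicate number as a block (replicate block), 281 miRNAs and 5 lists were called. Apart from the miR-29 and neural lists (adjusted p = 0.0526), miR-181a (0.0785) and miR-654-5p (0.0469), it changed no other call of a list or named miRNA. Leaving out 1 array moved the difference in detected miRNAs between -23.5 and -12.2 and that in the 75th percentile between -0.35 and -0.16. Each passed its threshold once, at the most negative value. Slide and scan blocks were not run, since there was 1 slide and 1 scan. Low signal leaves the 82 miRNAs below background in one group without a measured fold. With the normexp background, whose offset compresses dim signals, folds of 41 of 75 named miRNAs were over 1.5 times smaller, those of all 25 named miRNAs with a bound fell below it, and the calls of miR-141, miR-200c, miR-181a, miR-181c and miR-181d were lost.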

Other observations

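The miRNAs in this part were chosen after their values were seen, except those named in the report, and the 2 tests of strands and neighbours were also chosen after single fold changes had been seen, though before their own statistics were computed. Outside the lists, 226 miRNAs were tested, of which 99 rose, 82 fell and 45 were not past the threshold. miR-196a and miR-196b, both encoded in HOX clusters, fell by 2.80 (SE 0.08) and 3.45 (SE 0.08, above background on 2 of 4 Gα12QL arrays, so partly set by the floor) on the log2 scale, while miR-10a and miR-10b, also from HOX clusters, were among the largest increases. miR-193a-3p rose by 2.39 (SE 0.09) and its paralogue miR-193b fell by 2.75 (SE 0.08). miR-137, best known from neurons, rose by 3.25 (SE 0.03), and miR-361-5p by 3.94 (SE 0.06). Both strands of the miR-483 hairpin fell, miR-483-5p by 2.57 (SE 0.26). miR-33a, which lies in SREBF2 and restrains cholesterol export, fell by 2.57 (SE 0.20), and miR-185 by 2.59 (SE 0.05).

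A first hypothesis was that the changes are set before one strand of a hairpin is chosen. In 37 pairs of guide and star strand measured in both groups, the median absolute difference in log2 fold change was 0.47, against 1.17 for random pairings (permutation test with 100000 resamples, one-sided p = 8e-05, adjusted p = 8e-05 over 2 tests). Of 26 pairs with both strands changed, 22 went the same way and 4 opposite ways. This is consistent with changes in hairpin supply for most pairs. The opposite pairs were those of miR-125a, miR-22, miR-324 and miR-34a, whose star strand rose by 0.26 (SE 0.04) while miR-34a fell.

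A second hypothesis was that changes follow shared transcripts. Among 152 hairpins with 1 gene in the table, 21 clusters held 53 miRNAs within 10 kb of each other, and the median over clusters of the mean absolute difference was 0.46, against 1.85 for random placings (permutation test with 100000 resamples, one-sided p = 3e-05, adjusted p = 6e-05 over 2 tests). Of 36 neighbouring pairs with both changed, 32 went the same way. The 4 opposite pairs were let-7e with miR-99b and with miR-125a-5p, let-7c with miR-99a, and miR-191* with miR-425. The paralogous clusters of miR-23a and miR-27a and of miR-23b and miR-27b moved in opposite directions. miR-24-1*, a strand specific to the second cluster, was called lower, but was at the floor on all 4 Gα12QL arrays, so its size of change is not given. This may point to transcription of the host genes as the level of change, though probes of related neighbours can also read each other.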
